A study of Mus musculus with 4 samples.

How the data were processed

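ATAC-seq peaks were available for 4 libraries of mouse pachytene spermatocytes, 2 treated with BMH-21 and 2 with DMSO (mock). Per the labels' protocols, about 10000 cells per sample were tagmented, the libraries were amplified with 14 PCR cycles and sequenced as paired 150 bp reads, and sequencing to a stated minimum depth was planned. The series' design text names an RNA library kit, while the extract protocol names a tagmentation kit, and the latter is the one that fits the assay. The submitters' processing notes name fastp, Bowtie2, bedtools, deepTools and MACS2 2.1.0, without role or order. Peak calling parameters, the removal of duplicate or mitochondrial reads and any shift of read ends for the transposase were not given in the sources used here.

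Each library had its own narrowPeak list, so peaks were called per library and not on pooled samples. The deposited fold of each peak is a ratio of the fragment pileup at the summit to the local background of the same library. The deposited −log10 p and −log10 q describe that enrichment within 1 library, with a smallest −log10 q of 2.01 to 2.09, and the deposited score is 10 times the −log10 q cut to a whole number. None of these values is normalised between libraries. They were used to describe, rank or filter peaks within a list, and presence or absence of a peak was compared between lists. A peak that is absent fell below the threshold of the authors' caller in that library, which is not the same as closed chromatin.

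The submitters' processing notes name both mm39 and mm10. The coordinates were taken as mm10, since peaks on chromosome 1 reach position 195371801, which lies beyond the end of that chromosome in mm39, and since 61.0 to 70.7% of 21883 protein-coding genes of the GRCm38.p6 annotation had a peak within 1 kb of a gene end, against 14.8 to 29.4% after a shift of 50000 bp. Positions are 1-based. The annotation table used gives the start and end of 49939 genes on chromosomes 1 to 19, X and Y, without strand, transcripts or exons, and no genome sequence was used. The promoters, exons and introns planned beforehand were therefore replaced by gene ends (within 1 kb of either end of a gene), gene bodies and intergenic sequence. The planned analyses of CpG content and sequence motifs, and the use of single transcript starts, were not run and are not analysed here. A gene end can be the start or the end of transcription.

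Peaks were merged across libraries into regions when they overlapped by at least 1 bp, and a library held a region if any of its peaks overlapped it. A region or gene end is called mock-only, or lost, if it was in both mock and neither BMH-21 library, and BMH-21-only, or gained, in the reverse case. For a gene, a peak near either end counts in each library, and of the 4351 mock-only and 653 BMH-21-only genes 35 and 6 had no single end with a peak in both libraries of the group. Strength is the mean percentile of the fold within the 2 mock lists, divided into 10 classes. The matched difference is the observed share of mock-only regions minus the share expected from autosomal regions of the same strength classes. The summit pileup and the local background were recovered from the fold and p of each peak by the Poisson relation of the peak caller, with a largest error of 0.0008 in −log10 p. The smallest background of a list was taken as the genome-wide background, which scales with all reads given to the caller and does not separate nuclear from mitochondrial reads.

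Group means were compared with exact permutation tests over the 3 splits of 4 libraries, and X with the autosomes by its rank among 20 chromosomes. Shares have exact Clopper-Pearson 95% intervals. The 19 gene lists were tested with Fisher's exact test and with 10000 random lists matched on strength (a permutation of gene labels within strength classes), with Benjamini-Hochberg adjustment and a threshold of 0.05. Lists with fewer than 3 genes in the background were given as values only. Of the listed symbols, 5 were not in the annotation. Comparisons, gene lists and most alternatives were fixed before the data were examined. Named genes were the 10 protein-coding genes with the strongest mock-only and BMH-21-only peaks each, up to 4 lost and 4 gained members per list, the 5 strongest lost genes each on X and Y, and a fixed set of genes given in every case. No Y gene was lost.

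The alternatives tried were a stricter threshold (−log10 q of at least 5), lists cut to equal length, peaks cut to 100 bp on either side of the summit, a minimum overlap of 50%, gene-end windows of 500 bp and 2.5 kb, a looser definition of mock-only, and leaving out each library. Alternatives chosen after seeing the data were protein-coding or autosomal genes only, autosomes or X only, the same gene end required in both libraries of a group, and strength by −log10 q or by pileup. The procedures were tested on simulated data made from the first mock list of 109230 peaks, with loss shares of 20% on X and 60% on the autosomes, and returned 19.7% and 59.9%. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.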

Results

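Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts open DNA, in pachytene spermatocytes from mouse testis. Pachytene is the meiotic stage at which the autosomes are fully paired, while the largely unpaired X and Y are packed into the transcriptionally silenced XY body. The cells were exposed for 12 h to 2.5 µM BMH-21, an inhibitor of RNA polymerase I (the enzyme that transcribes pre-rRNA), or to DMSO alone (mock). Each group had 2 libraries, described by the submitters as biological replicates, and each library had its own list of peaks. Whether the replicates came from separate animals was not stated, so their spread may be partly technical. The mock lists held 109230 and 117905 peaks and the BMH-21 lists 51234 and 55459 peaks. Read totals were not given, but the genome-wide background per library, which scales with the number of reads used for peak calling, was recovered from the peak statistics. It was 4.54 and 4.31 fragments in the mock libraries and 4.46 and 4.11 in the BMH-21 libraries.

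The comparison of the treated with the mock cells asks how inhibition of RNA polymerase I alters genome accessibility, with the XY body named as the site of interest. Peaks on the autosomes were far fewer after BMH-21, whereas most peaks on X were still called. The mean number of autosomal peaks was 93736 ± 5028 (SD, n = 2) in mock and 36499 ± 2263 (SD, n = 2) in BMH-21 libraries, a ratio of 0.389. On X the means were 19633.5 ± 1081 and 16573 ± 690 (SD, n = 2 each), a ratio of 0.844. On Y the lists held 180 and 216 peaks in mock and 250 and 299 in BMH-21 libraries, a ratio of 1.39. The X chromosome accordingly held 17.3% of the peaks in each mock library (exact binomial 95% intervals 17.1 to 17.5%) and 31.4% (31 to 31.8%) and 30.8% (30.4 to 31.1%) in the BMH-21 libraries. For every one of these measures the groups did not overlap, and the exact permutation test over the 3 splits of the 4 libraries gave p = 0.33 (two-sided), the smallest p that 2 against 2 libraries allow. The intervals here and below cover counting error only.

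**Figure D1:**
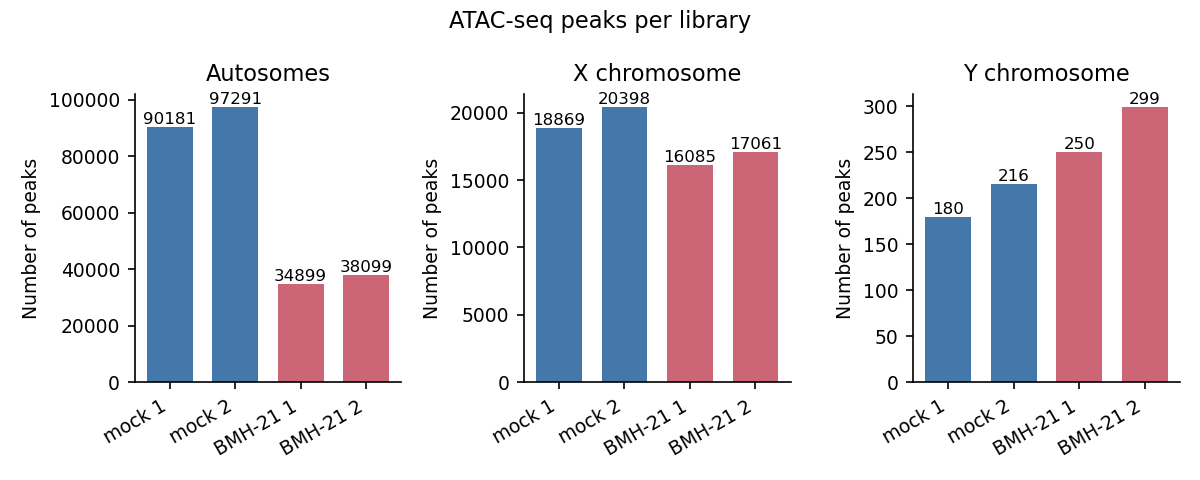
Number of ATAC-seq peaks (y axis, from 0, a separate scale per panel) in each of the 4 libraries on the autosomes, X and Y; each bar is 1 library (blue, mock; red, BMH-21), with its count above it. Autosomal peaks numbered 90181 and 97291 in mock and 34899 and 38099 in BMH-21 libraries, while X peaks numbered 18869 and 20398 against 16085 and 17061.

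The density of peaks showed the same contrast. Autosomes carried 36.6 and 39.5 peaks per Mb in mock and 14.2 and 15.5 in BMH-21 libraries. X carried 110 and 119 peaks per Mb in mock and 94.1 and 99.8 in BMH-21 libraries, and Y between 1.98 and 3.29 in all 4. Peaks covered 52.4 and 55.5 Mb in mock and 26.9 and 27.4 Mb in BMH-21 libraries. When each list was limited to its strongest 51234 peaks, which sets the ratio of peak numbers to 1, X still held 20.6 and 20.1% of the mock lists against 31.4 and 30.0% of the BMH-21 lists.

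Merging the 4 lists gave 155908 regions. Of these, 48289 were present in both mock and neither BMH-21 library (mock-only), 6794 were present in both BMH-21 and neither mock library (BMH-21-only), and 29225 were present in all 4. No pairing of 1 mock with 1 BMH-21 library held more than 1151 regions of its own. Libraries of the same group shared more of their covered bases than libraries of different groups. The Jaccard index was 0.639 between the mock libraries, 0.628 between the BMH-21 libraries and 0.307 to 0.315 between groups (exact permutation p = 0.33, the smallest possible over 3 splits). The size of the classes depended on the length of the lists. With equal list lengths, the strongest 51234 peaks of each, there were 14479 mock-only and 12194 BMH-21-only regions. Without the first mock library the mock-only class held 75027 regions, and without the first or the second BMH-21 library the BMH-21-only class held 14409 or 12174.

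The autosomes lost regions to a similar extent, and X stood apart from them. Of 70241 autosomal regions present in both mock libraries, 44738 (63.7%, 95% interval 63.3 to 64.0%) were mock-only, with a mean over the 19 autosomes of 63.7 ± 1.74% (SD) and a range from 61.0% on chromosome 11 to 67.3% on chromosome 12. On X, 3500 of 15877 regions (22.0%, 21.4 to 22.7%) were mock-only. X had the lowest share of the 20 chromosomes (exact permutation over chromosomes, two-sided p = 0.05, the smallest possible). This test, here and below, ranks chromosomes within the same 4 libraries and does not measure variation between libraries. On Y, 51 of 148 regions (34.5%, 26.8 to 42.7%) were mock-only. The contrast between X and the autosomes was present in each of the 4 pairs of a mock with a BMH-21 library, where 37.9 to 41.7% of X regions and a mean of 72.4 to 74.7% of autosomal regions were absent from the treated library. With equal list lengths the mock-only shares were 12.5% on X, 22.2% on Y and a mean of 41.6% on the autosomes, and without the second BMH-21 library the share on X was 34.3%. BMH-21-only regions made up 19.5% of the autosomal regions held by both BMH-21 libraries, 11.9% of those on X and 35.7% of the 157 on Y.

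**Figure D2:**
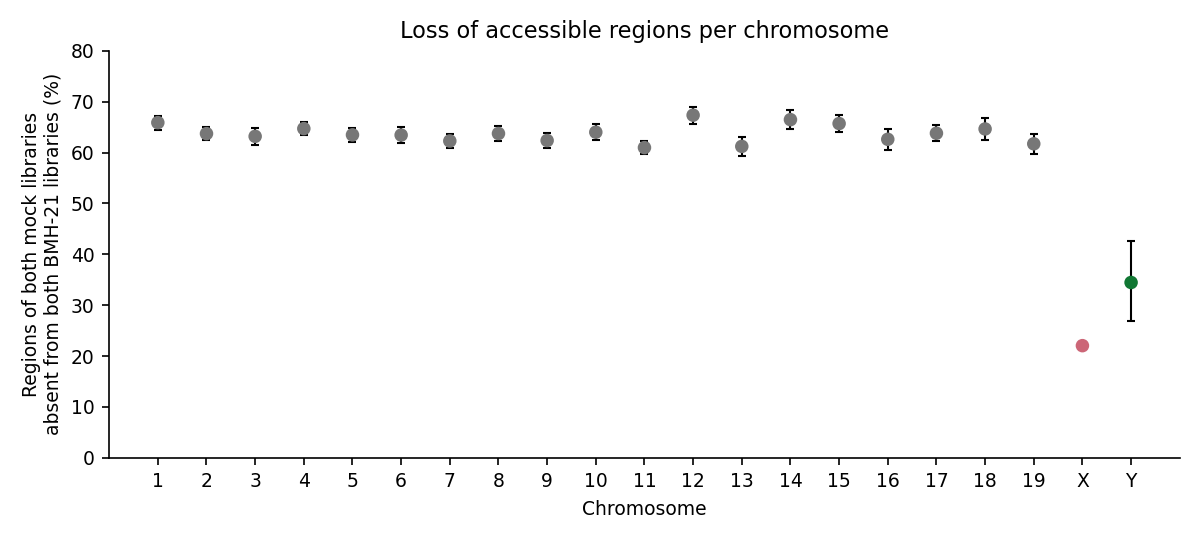
Percent of regions present in both mock libraries that were absent from both BMH-21 libraries (y axis) for each chromosome (x axis; grey, autosomes; red, X; green, Y), with exact binomial 95% intervals as bars (on X narrower than the point). X lies at 22.0%, below the lowest autosome at 61.0%.

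The contrast held among regions of equal strength. Regions were ranked by the fold enrichment that the authors' peak caller gave each peak, a value used here only to rank or describe peaks within a list. From the weakest to the strongest of 10 classes, the mock-only share went from 83.9% to 13.5% on the autosomes and from 66.7% to 1.39% on X, and X was lower in each class. Relative to autosomal regions of the same strength, X lost 33.9 percentage points fewer of its regions, whereas single autosomes deviated by -5.43 to 5.38 points (exact permutation over chromosomes, p = 0.05, the smallest possible). The size of this difference depended on the processing and ranged from -26.1 points without the second BMH-21 library to -53.8 points with strength taken as the fragment pileup at the summit, an alternative chosen after seeing the data. The retained X regions were spread along the chromosome, since the bins of 10 Mb with at least 20 regions had mock-only shares of 15.6 to 27.1%. The last bin held 9 regions, 3 of them mock-only.

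**Figure D3:**
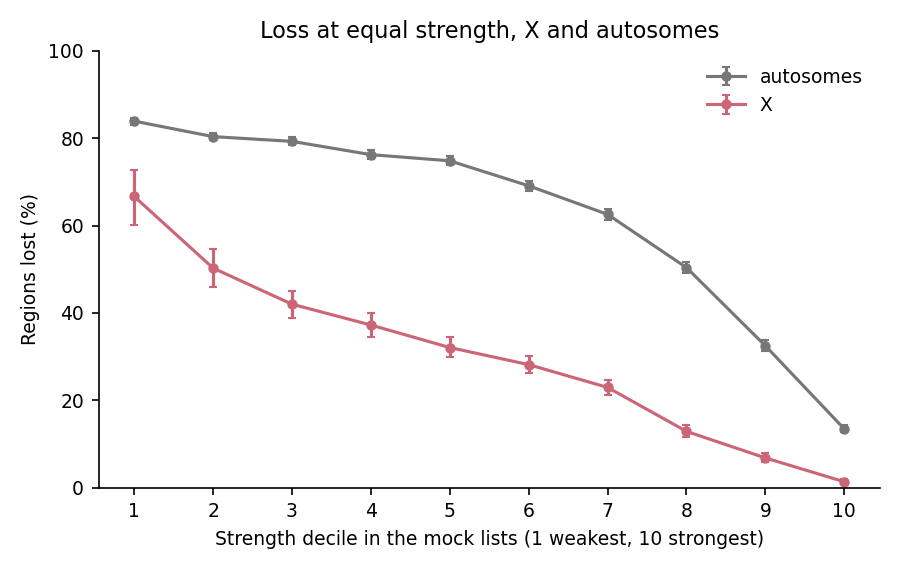
Percent of regions present in both mock libraries and absent from both BMH-21 libraries (y axis) by strength class in the mock lists (x axis, 1 weakest to 10 strongest), for X (red) and the autosomes (grey), with exact binomial 95% intervals. X lies below the autosomes in each class, from 66.7% against 83.9% in class 1 to 1.39% against 13.5% in class 10.

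On the autosomes, regions at gene ends were kept more often than regions inside genes or between them. A region within 1 kb of either end of an annotated gene was mock-only in 6078 of 19277 cases (31.5%, 30.9 to 32.2%), a region elsewhere in a gene in 26836 of 35675 (75.2%, 74.8 to 75.7%), and an intergenic region in 11824 of 15289 (77.3%, 76.7 to 78.0%). With equal list lengths the shares were 16.4%, 58.7% and 64.9%. Relative to autosomal regions of the same strength, gene ends lost 18.9 percentage points less and intergenic regions 11.2 points more (matched differences of -18.9 and 11.2). On X the corresponding shares were 18.2%, 26.0% and 21.0%. Gene ends accordingly held 24.1 and 23.0% of autosomal peaks in mock and 42.7 and 41.2% in BMH-21 libraries, whereas on X they held 8.71 and 8.41% in mock and 8.77 and 8.33% in BMH-21 libraries.

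**Figure D4:**
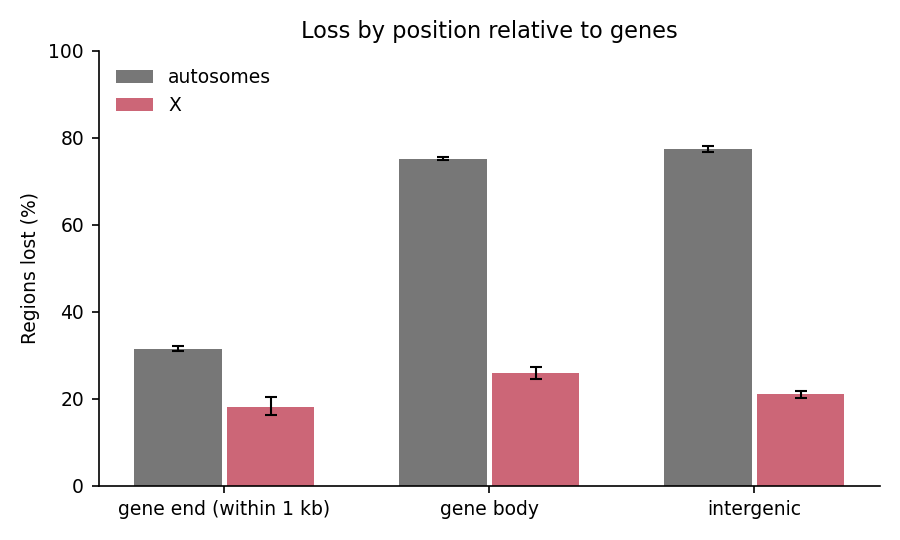
Percent of regions present in both mock libraries and absent from both BMH-21 libraries (y axis, from 0) by position relative to genes (x axis), for the autosomes (grey bars) and X (red bars), with exact binomial 95% intervals. Autosomal gene ends lost 31.5% of their regions and autosomal intergenic regions 77.3%, against 18.2% and 21.0% on X.

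The strongest autosomal mock-only region lay on chromosome 18 from 90601798 to 90602303 (mm10), between genes, with fold enrichments of 19.8 and 21.6 in the mock libraries. Others lay within the glutamate receptor gene Grik2 on chromosome 10 (49788389 to 49789113, fold 15.4 and 15.4) and within Spag16, a gene of the sperm axoneme, on chromosome 1 (70202742 to 70203620, fold 14.8 and 15.3). The strongest BMH-21-only region lay on chromosome 13 from 58732637 to 58733192, between genes, with folds of 16.3 and 15.7 in the BMH-21 libraries. Further BMH-21-only regions lay within Npas3 on chromosome 12 (53293893 to 53294309, fold 14.9 and 17.4) and Epb41l3 on chromosome 17 (69225636 to 69226584, fold 14.6 and 15.6).

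Most genes with an accessible end in mock cells kept it. Of 15036 protein-coding genes with a peak within 1 kb of an end in both mock libraries, 1735 (11.5%, 11 to 12.1%) had none in either BMH-21 library and 12675 had one in all 4 libraries. The share was 11.7% on the autosomes (1685 of 14367) and 7.51% on X (50 of 666, 5.62 to 9.78%). A further 175 protein-coding genes had a peak in both BMH-21 and neither mock library. With equal list lengths 7.02% were mock-only and 497 genes were BMH-21-only. The mock-only genes with the strongest peaks were D830030K20Rik and Gm38690, which share a peak on chromosome 14 (3208376 to 3209137, fold 17.1 and 15.2), Gm4736 (fold 14.0 and 15.1), Sema3c, which encodes a secreted semaphorin (chromosome 5, 17574399 to 17575299, fold 13.7 and 14.5), Gm3558, Gm8108, Acot12, an acetyl-CoA hydrolase (fold 12.7 and 14.0), Sybu, Slc1a6, a glutamate transporter (fold 13.4 and 12.9), and Thsd7a. Gm3558 and Gm8108 also lay on chromosome 14 (peaks at 7567919 to 7568664 and 4110011 to 4111110 in the first mock library). Whether the chromosome 14 genes were lost independently of each other was not tested. The BMH-21-only genes with the strongest peaks were Zfp930, which encodes a zinc finger protein (chromosome 8, 69208879 to 69209260, fold 12.5 and 15.0), Gm17768 (fold 12.5 and 17.4), Fez1 (fold 13.5 and 12.9), Gm6712, Ermap, Got1l1, Ifi44, Rab3c, Gm11543 and Igsf23. Of these, Ermap, Ifi44, Rab3c and Gm11543 were no longer BMH-21-only with a window of 500 bp, nor Ermap and Igsf23 with 2.5 kb, nor Ermap and Ifi44 with summit windows.

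Gene lists fixed before the data were examined were compared with all annotated genes that had a gene-end peak in both mock libraries, of which 19.5% (4351 of 22346) were mock-only, by Fisher's exact test (two-sided) with Benjamini-Hochberg adjustment over the lists. Genes are not replicates, so these tests describe these 4 libraries. None of 75 cytoplasmic ribosomal protein genes was mock-only (adjusted exact p = 3.12e-06), against 13.9% in random lists of the same strength (adjusted permutation p = 0.0036, the smallest that the 10000 random lists can give). The random lists were matched on strength and not on gene class, and 11.5% of all protein-coding genes were mock-only. Only 1 of 47 genes of the nucleolus and of pre-rRNA processing was mock-only, the acetyltransferase gene Nat10 (adjusted exact p = 0.00581). Its peaks were weak, with folds of 2.1 and 2.58. None of 36 genes of synapsis and meiotic recombination was mock-only (adjusted exact p = 0.00581). These last 2 lists did not pass against random lists of the same strength (adjusted permutation p = 0.142 each) or among protein-coding genes only (adjusted exact p = 0.172 and 0.109), and the synapsis list did not pass with equal list lengths (adjusted exact p = 0.128).

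The remaining germ cell lists did not pass the threshold for loss. None of 12 RNA polymerase I genes was mock-only (adjusted exact p = 0.26), nor any of 12 pachytene transcription regulators (adjusted exact p = 0.26) or 8 autosomal retrocopies of X-linked genes (adjusted exact p = 0.474). Polr1a, the gene for the largest subunit of the polymerase, had a peak in all 4 libraries. The gene for the meiotic transcription factor Mybl1, the synaptonemal complex gene Sycp3 and the testis-specific ribosomal gene Rpl10l also had a peak in all 4 libraries. Ubtf, which encodes a pre-rRNA transcription factor, had a peak only in the first BMH-21 library. Of the XY body and DNA damage response genes, 1 of 23 was mock-only, Trp53bp1 (adjusted exact p = 0.175), and of the piRNA pathway genes 1 of 17, Fkbp6 (adjusted exact p = 0.366). Of 28 spermiogenesis genes 5 were mock-only (adjusted exact p = 1), among them the protamine genes Prm1 (fold 3.83 and 5.00 in mock), Prm2 and Prm3, the last 2 through a shared peak, and the kinase gene Tssk2. Tdrd7 and Tdrd6 of the piRNA pathway and Spaca4 and Spaca3, genes of acrosomal proteins, were BMH-21-only. For gains, the spermiogenesis list had 2 of 12 genes (adjusted exact p = 0.151). It passed under the stricter threshold, equal list lengths, summit windows, a 500 bp window and without either mock library (adjusted exact p = 0.0255 to 0.0471), but not under the other alternatives (adjusted exact p up to 0.334).

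On the sex chromosomes, 1 of 33 X-linked genes used in most cells was mock-only, Xiap (adjusted exact p = 0.0607), and 0 of 16 X-linked germline genes (adjusted exact p = 0.163). Both lists were compared with genes of all chromosomes and classes. On X itself, 10.1% of all genes with a peak in both mock libraries and 7.51% of the protein-coding ones were mock-only. Whether the lists differ from other X genes was not tested. The peaks of Xiap in the 2 mock libraries lay at opposite ends of the gene (42109914 to 42110121 and 42060357 to 42060569), and it was not mock-only when the same end was required, an alternative chosen after seeing the data. The first of these lists passed the threshold without any 1 of the 4 libraries and with summit windows, a window of 500 bp or 2.5 kb or the same gene end required (adjusted exact p = 0.0072 to 0.0475). It did not pass with equal list lengths, the stricter threshold or protein-coding genes only (adjusted exact p = 0.133, 0.164 and 0.425), nor against random lists of the same strength (adjusted permutation p = 0.142). Rpl10 had a peak in all 4 libraries. The mock-only X genes with the strongest peaks were Nudt10 (fold 7.04 and 8.47), Tceanc, Nudt11, Alas2, the erythroid enzyme of haem synthesis, and Trmt2b, a tRNA methyltransferase. Of 10 Y-linked genes without a mock peak, 3 had a peak in both BMH-21 libraries (adjusted exact p = 0.0147), against 2.59% of other genes. These were Usp9y, a deubiquitinase gene (Y, 1459272 to 1459956, fold 8.55 and 7.96), Zfy2, a zinc finger gene (fold 5.23 and 5.28), and Uba1y (fold 6.33 and 5.12). The Y list was likewise compared with genes of all chromosomes and classes. Of 375 annotated Y genes without a mock peak 5 were BMH-21-only, as were 35.7% of the Y regions held by both BMH-21 libraries. Whether the list differs from other Y genes was not tested. Zfy1 had a peak only in the first BMH-21 library.

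Markers of other cells that a testis preparation can hold were also tested. Of 9 leukocyte genes with a mock peak 5 were mock-only, among them C1qc, C1qa, Tyrobp and Fcer1g (adjusted exact p = 0.0629, and 0.0129 to 0.14 under the alternatives, on both sides of the threshold). Random lists of the same strength lost 36.4% (adjusted permutation p = 0.891). Of 13 Sertoli cell genes 4 were mock-only, namely Kitl (fold 9.46 and 10.5), Inha, Sox8 and Gata1 (adjusted exact p = 0.41). The counts were 3 of 11 for Leydig and peritubular cells, namely Tcf21, Star and Nr5a1 (adjusted exact p = 0.549), 2 of 7 for endothelial cells, Cdh5 and Tie1 (adjusted exact p = 0.707, but 66.7% and 0.0413 with a 500 bp window and 0% and 0.466 with a 2.5 kb window), and 2 of 16 for spermatogonia, Dmrt1 (fold 8.29 and 7.52) and Ccnd2 (adjusted exact p = 0.797). In the Sertoli list Rhox5 was BMH-21-only.

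Stress-related lists did not pass the threshold either. Of 27 p53 target genes 2 were mock-only, Cdkn1a, the cell cycle inhibitor (fold 3.63 and 3.29), and Fas (adjusted exact p = 0.26), while Mdm2 had a peak in all 4 libraries. The strongest Cdkn1a peak of the first mock library (29099925 to 29100491) lay near the higher end of the gene (29090979 to 29100722). As for every gene named here, strand was not available. A lost gene-end peak is therefore not necessarily a lost promoter peak. The Mdm2 peak ranked lower after treatment, with fold percentiles of 91.3 and 90.9 in the mock lists and 29.8 and 40.7 in the BMH-21 lists. A lower rank was not particular to Mdm2. The peaks of Mybl1, Polr1a, Sycp3, Rpl10l and Rpl10 also ranked lower, by smaller steps. For Polr1a the percentiles were 94.3 and 94.6 in the mock and 71.8 and 66.3 in the BMH-21 lists. The lists differ in length and composition, so percentiles are not directly comparable between them. Of 23 immediate early and stress response genes 2 were mock-only, Ier2 and Myc (adjusted exact p = 0.41). The nucleolar gene Nop10 and the ribosomal gene Rpl22 were BMH-21-only within 1 kb. Ribosomal protein genes gained a peak in 1 of 3 cases (adjusted exact p = 0.152). The share was 50% with equal list lengths (adjusted exact p = 0.0461) and 0% with summit windows or a 500 bp window (adjusted exact p = 1).

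Some of the calls for single list members and X genes depended on the processing. With a window of 2.5 kb the loss ended for Fkbp6, Dmrt1, Inha, Sox8, Gata1, Nr5a1, Cdh5, Tie1, Nat10, Ier2, Xiap, Nudt11 and Alas2 and the gain for Tdrd7, Tdrd6, Spaca4, Rhox5, Nop10 and Rpl22. With a window of 500 bp the loss ended for Star and Xiap and the gain for Tdrd6, Rhox5 and Rpl22, and with summit windows the gain for Tdrd6 and Rpl22. With equal list lengths the loss ended for Fkbp6, Prm1, Star, Nr5a1, Fcer1g, Tie1, Nat10, Fas and Xiap, and with the stricter threshold for Nat10. Without the second BMH-21 library Ubtf and Zfy1 counted as gained.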

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

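The tests of read depth, of a uniform fall of signal, of region strength and of regional coverage on X were chosen after the results were seen.

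The local background around X peaks, a value outside the comparisons of peak presence, was higher in both BMH-21 libraries than in the mock libraries. Its median, relative to the genome-wide background of the same library, was 1.41 in the first and 1.55 in the second BMH-21 library, against 1.00 in both mock libraries. The mock medians sit at the lowest value the peak caller allows. The share of X peaks at that lowest value was 53.3 and 51.6% in mock and 15.4 and 11.4% in BMH-21 libraries. At the 8750 X regions held by all 4 libraries it was 57.3 and 53.3% in mock and 14.5 and 9.07% in BMH-21 libraries.

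The first pattern is the smaller number of peaks in the BMH-21 libraries. Lower read depth is argued against by the genome-wide background, whose ratio of means was 0.968, and by the first BMH-21 library, which had 1.03 times the background of the second mock library and 0.435 times its peaks. This holds for all reads given to the caller, since the background does not separate nuclear from mitochondrial reads. As a fragment pileup it also depends on fragment length, which was not compared. A uniform fall of signal over background, or of nuclear reads, is argued against as the sole cause by the matched difference on X of -33.9 percentage points, although at regions held by all 4 libraries, which were selected for being kept, the median summit pileup was lower after BMH-21 on the autosomes (90 and 92 fragments in mock, 72 and 74 in BMH-21 libraries) and on X (38 and 38, 31 and 32) alike. Fewer cells of other types in the treated samples remain open, since the 5 marker lists together lost 16 of 56 genes against 14.7 expected at the same strength (permutation p = 0.769 from strength-matched random lists), and the peak lists do not give cell shares. An effect of BMH-21 on autosomal accessibility, and a change in the stage or viability of the spermatocytes during the 12 h of treatment, also remain open and untested.

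The second pattern is the retention of X regions. A greater strength of X regions in mock is argued against by the matched difference of -33.9 percentage points, and a few stretches of X by the bins of 10 Mb with at least 20 regions, of which 100% lay below the lowest autosome. A rise of coverage over X in the BMH-21 libraries was also considered. The local background at X peaks was 1.48 times that in mock, against 1.04 times on the autosomes, where it fell at regions held by all 4 libraries (2.50 and 2.60 in mock, 2.15 and 2.26 in BMH-21 libraries), and this criterion alone, the one first set, was met. A second criterion was added only after its value was seen, namely that X summits rise relative to autosomal summits at the regions held by all 4 libraries. There the X to autosome ratio of median summit pileup was 0.422 and 0.413 in mock and 0.431 and 0.432 in BMH-21 libraries, 1.03 times higher. Relative to the genome-wide background, the median X summit there was 8.37 and 8.81 in mock and 6.96 and 7.78 in BMH-21 libraries. A higher local background without higher summits lowers the fold and so would hinder the calling of X peaks. With both criteria, the explanation is left undecided, also because these regions were selected for being kept. A biological difference of X chromatin in its response to the treatment stays open as a hypothesis.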

How the results depend on the processing

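Libraries share only a replicate number across groups. Taking it as a replicate block gave a mean peak ratio of 0.470 and an exact permutation p of 0.5, the smallest that 2 pairs allow, and changed no call, since presence classes are the same under any pairing. At the 29225 regions held by all 4 libraries, the difference in fold percentile between the replicates of a group had a correlation of 0.00234 between mock and BMH-21.

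No result past its threshold in the main analysis turned its direction. Some lists that passed neither there nor under the alternative named lay on the other side of the background. For losses these were Leydig and peritubular cells against random lists of the same strength (27.3%), spermiogenesis with equal list lengths (12.0%), a 2.5 kb window (20%) and protein-coding genes only (17.9%), spermatogonia with equal list lengths and protein-coding genes only (12.5% each), and Sertoli (18.75%) and endothelial cells (0%) with a 2.5 kb window. Leaving out 1 library gave 17.9 to 27.3% for spermiogenesis and 11.8 to 25.0% for spermatogonia. For gains these were Leydig and peritubular cells with equal list lengths (12.5%), ribosomal proteins with summit windows or a 500 bp window (0%), and Sertoli cells with either other window or autosomal genes only (0%).

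With the stricter threshold, the within-group minus between-group overlap was 0.335, the X minus autosome loss -37.5 percentage points, the gene end minus intergenic loss -46.4 points, and 3 lists passed for gains. With equal list lengths, which by construction set the peak ratio to 1, there were 14479 mock-only and 12194 BMH-21-only regions, an overlap difference of 0.288, an X difference of -29.1, a gene-end difference of -48.5 and 4 lists for gains. With summit windows these were 10578 BMH-21-only regions, 0.256, -43.1 and -34.7, with 5 lists for losses and 2 for gains. A 50% overlap gave -42.4 and -44.8. A 500 bp window gave a gene-end difference of -53.2, with 6 lists for losses and 2 for gains, and a 2.5 kb window -35.3. Among alternatives chosen after seeing the data, the peak ratio was 0.389 for autosomes and 0.844 for X, and 0 lists passed for gains without the sex chromosomes, where the Y-linked list cannot be tested. The matched X difference was -45.1 with strength by −log10 q and -53.8 by pileup, against -26.7 with equal list lengths, -30.8 with the stricter threshold, -37.2 with summit windows, -35.3 with a 50% overlap and -33.9 to -26.1 without 1 library.

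Leaving out 1 library gave 52320 to 75027 mock-only and 8061 to 14409 BMH-21-only regions, an overlap difference of 0.313 to 0.328, an X difference of -42.6 to -33.5, a gene-end difference of -46.3 to -43.4, 4 to 5 lists for losses and 1 to 4 for gains. The group then rests on 1 library, so fewer absences or presences are required. Autosomal gene ends lost 23.8% with a 500 bp window, 42.5% with 2.5 kb and 44.3% with summit windows. Protein-coding genes with a BMH-21-only peak numbered 175, or 497 with equal list lengths. The cause of the other shifts was not tested. Of the comparisons of named genes with alternatives, 653 gave the same state and 47 another. The longest transcript start, CpG and motif alternatives were not run. Depth limits weak peaks most, and read totals are unknown.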

Other observations

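The gene families and the tests of families, the gene classes and the members named here were chosen after the data were seen, and the tests of strong autosomal regions were set before their results.

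Among autosomal protein-coding genes, 178 families of at least 10 genes that share the start of their symbol were compared for loss with other such genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjustment), and 5 passed both this test and strength-matched random lists. All 11 Pcdhb genes with a mock peak, which encode clustered protocadherins of neuronal adhesion, were lost (adjusted exact p = 9.99e-09). The others were the hair keratin-associated genes Krtap with 11 of 12, the olfactory receptor genes Olfr with 15 of 21, the keratin genes Krt with 16 of 31 and the secreted protease genes Adamts with 11 of 23 (adjusted exact p = 3.57e-08, 2.5e-08, 2.84e-06 and 0.0007). The background was about 11.7% of other genes. Genes of a cluster can share peaks and are not independent. The related protocadherin genes Pcdhga lost 0 of 12, against 32.8% in random lists of the same strength (adjusted permutation p = 0.246). The zinc finger genes Zfp lost 15 of 305 and the translation initiation genes Eif 0 of 50, fewer than other genes (adjusted exact p = 0.00157 and 0.0394), but neither passed against random lists of the same strength (adjusted permutation p = 0.133 and 0.51). The families whose symbols start with Rpl and Rps lost 1 of 45 and 1 of 36. These families are defined by symbol and differ from the fixed list of cytoplasmic ribosomal proteins. None of the 75 genes of that list was lost, so the lost family members are not on it. Neither family passed either test (adjusted exact p = 0.314 and 0.409, adjusted permutation p = 0.443 and 0.854). Of 54 families tested for gains, the Zfp genes gained a peak in 10 of 69 cases against 2.71% of other genes (adjusted exact p = 0.000577), among them Zfp930, Zfp960 (fold 7.51 and 7.82) and Zfp454 (fold 6.23 and 6.45). Gains were fewer than among other genes for Olfr, with 2 of 1068, and the vomeronasal receptor genes Vmn, with 0 of 351 (adjusted exact p = 1.1e-10 and 0.000788). Strength matching was applied to losses only.

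The share of genes that lost a gene-end peak varied between gene classes, a difference that was neither tested nor matched on strength. The share was 68.5% for autosomal snoRNA genes (263 of 384) against 2.78% for those on X (1 of 36), and 58.8% for autosomal pseudogenes (641 of 1091) against 12.8% on X (57 of 447). It was 29.4% for lncRNA genes (1307 of 4451) and 11.6% for tRNA genes (17 of 146). Small genes within other genes take the peaks of their hosts. Of 63 annotated rRNA genes, 57 had a gene-end peak in neither mock library and 5 in both. These 5 had none in either BMH-21 library, namely n-R5s136, n-R5s146, Gm22291 and Gm23284 on chromosome 8, the last 2 through a shared peak, and n-R5s33 on chromosome 16. In the first mock library each of these peaks lay beside its gene and not over it. The chromosome 8 genes are neighbours, between positions 123599859 and 123620359, so their losses may not be independent. The pre-rRNA repeats that RNA polymerase I transcribes were not analysed here.

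The third pattern is a set of strong autosomal regions, at or above percentile 90 of their lists by fold, that were present in only 1 group. There were 1018 in mock and 276 in BMH-21 libraries. The other 2 splits gave 0 such regions (0% of the number), which argues against differences that fall on pairs of libraries at random. A difference carried by 1 library cannot enter any split, so the comparison of splits does not test it. Nor can this comparison exclude a difference between the groups as a whole that is not due to treatment, since each group had 2 libraries. Large segments that differ between the animals of the groups may account for some of the BMH-21-only regions, since 8.70% lay within 100 kb of another against 3.86% of random strong regions, a ratio of 2.25. The mock-only regions had a ratio of 1.07, and the labels do not say which animals were used, so this cannot be told apart from an effect of the treatment for the BMH-21-only regions.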
